A study of Mus musculus with 6 samples.

How the data were processed

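RNA-seq libraries of MC3T3-E1 pre-osteoblasts were compared between NU7441 at 1 µM and DMSO, each given for 16 h, with 3 samples per group. Per the labels' protocols, total RNA was isolated and libraries were made with an Illumina mRNA kit. The series' design text says that triplicates of independent experiments were pooled before sequencing, but not what a triplicate is or which experiment a sample number stands for, so p-values measure the spread between these samples. The submitters' processing notes name bcl2fastq, TopHat2 version 2.0.6, HTSeq and the genome build mm10 without their settings. Whether the counting used strand is not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. Genes named in the text that share positions with another gene in the table include Ccna2 (with Exosc9), Cdc20 (with Elovl1), Tk1 (with Afmid), Ogn (with Cenpp), Tagln (with Pcsk7), Dkc1 (with Mpp1), Ctsb (with Fdft1), Shmt2 (with Ndufa4l2), Runx2 (with Supt3h), Hist1h1e (with Hist1h2be), Rpl5 (with Fam69a) and Txnrd1 (with Eid3).

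The authors deposited a count, an RPKM value and a gene length for each of 23358 gene rows, per the file headers. The deposited counts are whole numbers with 0 odd values among them, so each read pair appears to have been counted as 2, and the totals lie between 47312968 and 71292628 counts per sample. Counts as deposited were tested, and counts divided by 2 were an alternative. The deposited RPKM values divide each count by the gene length and by one total per sample, which the gene counts fill to between 74.2% and 75.7%, and they were used only for that check. The gene length, per the file headers a coding length, is a multiple of 3 in 37.8% of rows. For 18566 protein-coding rows it was a median of 0.97 times the merged exons and 1.63 times the merged coding exons of GENCODE M21, and nearer the former in 81.1% of those where the 2 differ, so that for most it includes untranslated regions. Of the rows 5529 were at 0 in all samples, 26 symbols occurred more than once, and 0 columns of sample values were left unmapped. Of 20970 rows whose symbol is in the GENCODE M21 annotation, 99.4% overlapped the same gene on mm10. Coordinates are those of the deposited table on that build.

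Genes were filtered with filterByExpr at its default settings (minimum count 10, minimum total 15), scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with group as the only term, two-sided, and with Benjamini-Hochberg adjustment over all genes tested at a threshold of 0.05. The SE of a log2 fold change was its size divided by the square root of the F statistic. CPM values use the scaled library sizes. The biological coefficient of variation was 5.6%. Before the data were examined, 31 gene lists were fixed. Of these 30 had at least 5 tested genes and were tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01. None of the 13 called lists held at an adjusted p of 0.05 with an estimated correlation. The list of mitochondrially encoded transcripts had 0 rows in the table and was not analysed here. Lists for other cell types and for RNA quality were among those fixed.

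Genes named in the text followed a rule fixed before the data were examined. It took Prkdc, Naca, Jun, Runx2, Sp7, Alpl, Bglap, Bglap2, Ibsp, Spp1 and Col1a1 in any case. It added the 10 genes with the largest change in each direction among those that passed, averaged at least 1 CPM, did not overlap between groups and had no predicted or clone name, and up to 3 members of each list with the lowest adjusted p. Genes needed by a check in the closing section were also allowed by the rule and were chosen after seeing the values. Other genes are named as members of a fixed list or family after their values were seen, among them Fosl1, Rpl34 and Polr1c. Not every list member that the rule took is described in the text, and 1 result is not reported here.

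The procedure was tested on simulated counts drawn from the means and library sizes of these samples for NU7441 against DMSO. The genes changed in the simulation were drawn from those with a mean of at least 100 counts. Of these, edgeR recovered 64.2% of genes changed by 1.25-fold, 94% at 1.5-fold and 100% at 2-fold. Recovery of genes with fewer counts was not tested. Among the 13658 genes run, 13 of 185 calls (7%) were false, and 0 of 30 unchanged lists were called by camera with the preset correlation. Genes were simulated independently of each other. That last result therefore does not cover lists whose genes vary together, such as G2/M and mitosis (estimated correlation 0.762). Samples of one group differed from each other by more than sampling noise in every pair, so each was counted once. Separate libraries of 1 pooled RNA could differ in this way too, so the check does not show that the samples are independent cultures. In a principal component analysis of log2 CPM the first component held 42.5% of the variance and separated the groups. Alternatives were other scalings, filters and thresholds, DESeq2 1.42.0, limma-voom, the replicate number as a block, each sample left out in turn, an estimated correlation in camera, and fry. Added after seeing the data were halved counts, a robust fit, fits without Rn45s and Lars2 and without genes holding isolated count spikes, and a count restricted to groups that do not overlap. Checks of gene length and GC content and enrichment tests used Python 3.11.15 with scipy 1.17.1 and statsmodels 0.14.6. Lars2 can take reads from ribosomal RNA, and it held between 2.01% and 2.19% of the counts.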

Results

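RNA was measured in MC3T3-E1 cells, a line of mouse pre-osteoblasts from the calvaria of the C57BL/6 strain that can form bone matrix in culture. Confluent cultures had received either NU7441, an inhibitor of the DNA-dependent protein kinase (DNA-PK), at 1 µM or its solvent DMSO for 16 h. There were 3 sequenced samples per group, and the series' design text says that triplicates of independent experiments were pooled before sequencing. The DMSO samples held 55070554, 47312968 and 71292628 gene counts and the NU7441 samples 52150994, 55021692 and 52944350, so that depth differed most within the DMSO group. Total counts did not differ between the groups beyond that spread (exact permutation test, two-sided p = 0.7, n = 3 per group, where 0.1 is the smallest p that 3 against 3 samples allow). Rn45s, the ribosomal RNA precursor, took 13.3% ± 0.5 (SD, n = 3) of the counts in DMSO and 12.8% ± 0.5 in NU7441 (exact permutation test, two-sided p = 0.3).

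The comparison of NU7441 with DMSO asks which transcripts change when DNA-PK activity is inhibited in pre-osteoblasts. The series concerns the phosphorylation of the coregulator αNAC, the product of Naca, by the catalytic subunit of that kinase. Genes of cell division were lower in NU7441: Plk1, a mitotic kinase, fell from 33.1 ± 3.38 to 10.5 ± 2.07 counts per 1e6 counts (CPM, mean ± SD, n = 3), a log2 fold change of -1.66 ± 0.10 (SE; edgeR, adjusted p = 1.4e-08). Interferon-stimulated genes were higher, among them Irf7, a transcription factor of the interferon response, which rose from 2.89 ± 0.202 to 5.98 ± 1.52 CPM (log2 fold change 1.04 ± 0.16, edgeR adjusted p = 0.00021). Of the osteoblast genes, Ibsp, which encodes bone sialoprotein, fell by 0.89 on the log2 scale, whereas Runx2, the master regulator of the lineage, stood at 174 ± 5.95 CPM in DMSO and 176 ± 5.2 in NU7441 (edgeR, adjusted p = 0.81). Of 13784 genes tested with edgeR's quasi-likelihood test, 4231 passed a Benjamini-Hochberg adjusted p of 0.05, 1941 higher and 2290 lower in NU7441. With upper-quartile scaling 56.5% of 4407 calls were higher, against 45.9% in the fit with TMM scaling. Changes of at least 2-fold were found for 216 of the 4231 genes, 28 higher and 188 lower. In a fit without genes holding isolated count spikes, chosen after seeing the data, the number was 211. With halved counts, also chosen then, it was 194. It was 183 with DESeq2 and 225 without a filter on low counts. Every NU7441 sample lay on one side of every DMSO sample for 4116 of the called genes, and this held for 42.8% of all tested genes where chance gives 10%.

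**Figure D1:**
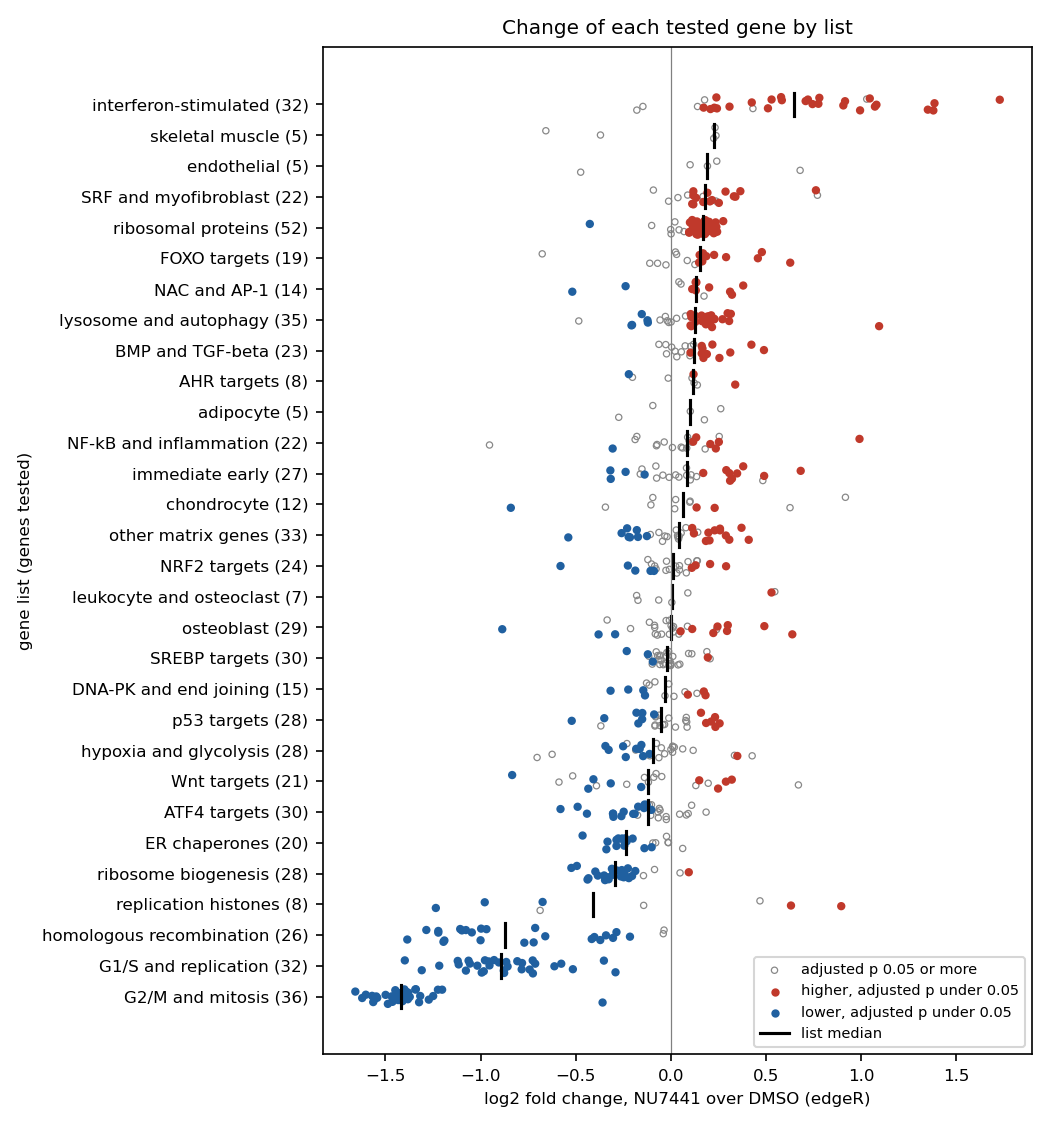
Each point is 1 tested gene of a list fixed before the data were examined, placed by its log2 fold change of NU7441 over DMSO (edgeR, 3 samples per group); filled points passed an adjusted p of 0.05 and black bars mark list medians. The medians run from -1.42 for the mitosis list to 0.65 for the interferon list.

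The mitosis genes fell together. All 36 tested genes of the G2/M and mitosis list were lower, 35 of them by at least 2-fold, with a median log2 fold change of -1.42. Aurka (-1.62 ± 0.10), Aurkb (-1.57 ± 0.06) and Ccna2 (-1.56 ± 0.09), which encode mitotic kinases and cyclin A2, were among the 10 genes with the largest falls, as were Cdc20 (-1.56 ± 0.10) and Pbk (-1.60 ± 0.06). The other members of those 10 were Depdc1a (-1.78 ± 0.12), Troap (-1.67 ± 0.10), Shcbp1 (-1.57 ± 0.11) and Neurl1b (-1.74 ± 0.19), which no list held, together with Plk1. Top2a, the topoisomerase of dividing cells, went from 397 ± 24.6 to 149 ± 12.3 CPM. The 32 tested genes of the G1/S and replication list also all fell, with a median of -0.89, and 9 of them by at least 2-fold. Rrm2, a subunit of ribonucleotide reductase, went from 72.5 ± 1.85 to 31.2 ± 1.05 CPM (log2 fold change -1.22 ± 0.04), and Tk1 (-1.31 ± 0.05) and Uhrf1 (-1.06 ± 0.04) fell too. Counts adjusted over the list alone were the same, 36 and 32. Against all other genes, camera gave an adjusted p of 7.3e-27 for the mitosis list and 1.5e-26 for the replication list, which became adjusted p = 0.29 and adjusted p = 0.18 with an estimated correlation. Replication-dependent histone genes, which largely lack poly(A) tails, had few counts and went both ways. Of 8 tested, Hist1h1c (0.63 ± 0.09) and Hist1h2bc (0.89 ± 0.18) rose and 3 fell, among them Hist1h1e (-0.98 ± 0.20), the same as adjusted over the list alone (camera, adjusted p = 0.55), and without DMSO replicate 1 the number that fell was 1.

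**Figure D2:**
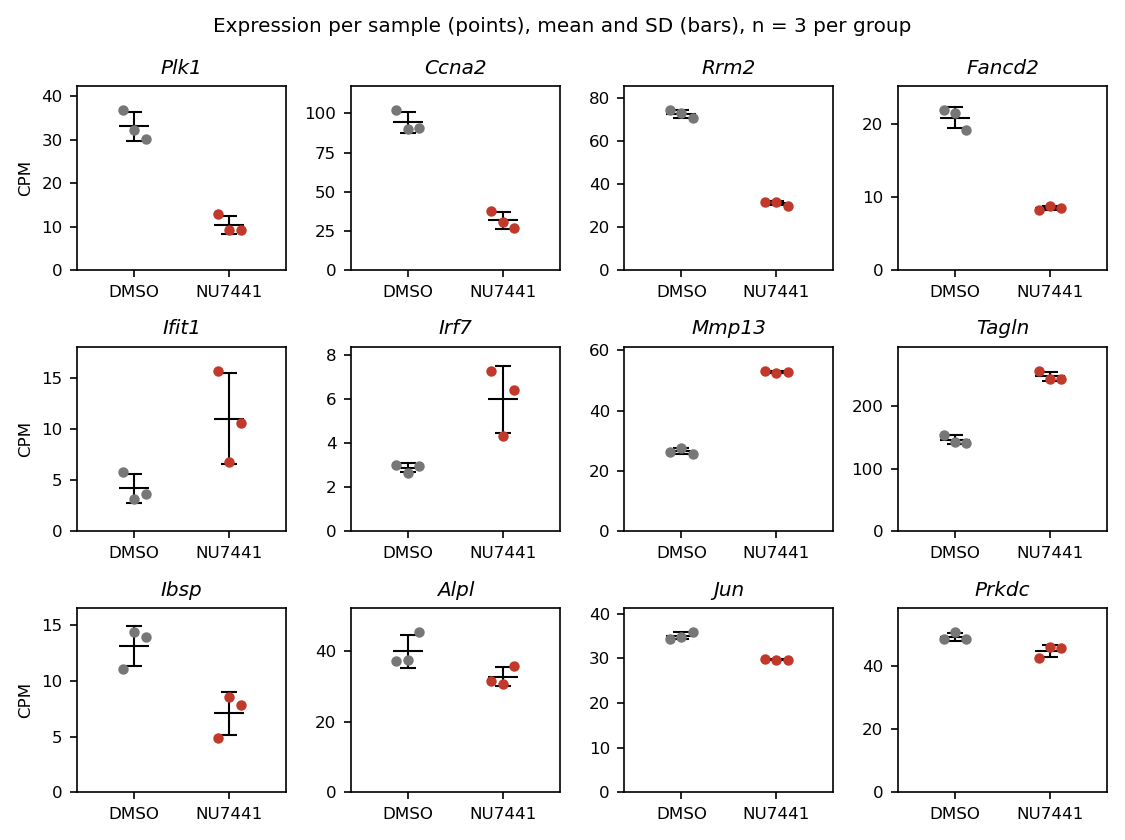
CPM in each of the 3 DMSO and 3 NU7441 samples (points), with the mean and SD of each group (bars), for 12 genes named in the text. The samples of the groups do not overlap for these genes, which the naming rule required of those with the largest changes. Named genes whose groups overlap, such as Runx2, Sp7 and Col1a1, are not shown. Ifit1 ranged from 6.84 to 15.7 CPM among the NU7441 samples.

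Genes of homologous recombination fell, and those of end joining went both ways. In the homologous recombination and Fanconi list 24 of 26 tested genes were lower and 0 higher, with a median of -0.87, both over all genes and as adjusted over the list alone. Fancd2, a Fanconi anaemia repair gene, fell from 20.9 ± 1.46 to 8.55 ± 0.251 CPM (log2 fold change -1.29 ± 0.07, edgeR adjusted p = 2.3e-09), and Brca1 by 1.10 on the log2 scale. Camera gave the list an adjusted p of 1.5e-16, and adjusted p = 0.18 with an estimated correlation. Prkdc, which encodes the catalytic subunit of DNA-PK (mm10 chromosome 16, 15637866 to 15842239), went from 49.4 ± 1.29 to 44.9 ± 1.94 CPM, a log2 fold change of -0.14 ± 0.04 (edgeR, adjusted p = 0.016). That call was lost without DMSO replicate 2 (adjusted p = 0.0611) and without NU7441 replicate 1 (adjusted p = 0.0546). Of the 15 genes of DNA-PK and end joining 4 fell, Rif1 (-0.32 ± 0.04), Xrcc6 (-0.22 ± 0.04), Xrcc5 (-0.15 ± 0.03) and Prkdc, and 3 rose, as they did adjusted over the list alone (camera, adjusted p = 0.53). The number that rose was 0 without DMSO replicate 3 and without NU7441 replicate 2. Of 28 tested p53 targets 6 rose and 7 fell (6 and 8 adjusted over the list alone), with Trp53inp1 (0.23 ± 0.04) and Xpc (0.23 ± 0.04) higher and Aen (-0.35 ± 0.04) lower, and camera gave an adjusted p of 0.62.

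Osteoblast genes did not move as a group. Ibsp (mm10 chromosome 5, 104299287 to 104311472) went from 13.1 ± 1.8 to 7.09 ± 1.94 CPM, a log2 fold change of -0.89 ± 0.15 (edgeR, adjusted p = 0.00041). Alpl, the alkaline phosphatase of mineralizing cells (mm10 chromosome 4, 137741732 to 137796377), went from 39.9 ± 4.68 to 32.7 ± 2.73 CPM (-0.29 ± 0.07, edgeR adjusted p = 0.006, and a log2 fold change of -0.19 for Alpl without DMSO replicate 3). Spp1, which encodes osteopontin, rose by 0.25 ± 0.03 (edgeR, adjusted p = 5.2e-06), and Ogn (0.49 ± 0.05) and Bmp4 (0.29 ± 0.04) rose too. Sp7 had a log2 fold change of -0.08 ± 0.06 (edgeR, adjusted p = 0.30, and 0.0306 without DMSO replicate 1) and Col1a1, at 18580 ± 699 CPM in DMSO, of 0.00 ± 0.02. Of 29 tested genes 8 rose and 3 fell (8 and 5 adjusted over the list alone), with median and mean both 0.00, and camera gave an adjusted p of 0.53. The number that fell was 6 without DMSO replicate 1, and the number that rose was 5 without NU7441 replicate 2. A robust fit, chosen after seeing the data, left 5 higher and 1 lower and gave adjusted p = 0.0589 for Ibsp and 0.095 for Alpl. Bglap and Bglap2, the osteocalcin genes, had from 2 to 12 counts per sample and were removed by the low-count filter. The main fit therefore gives no answer for them. The alternative without that filter tested all 35 genes of the list.

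Among NAC and AP-1 genes, Naca itself (mm10 chromosome 10, 128035346 to 128048637) rose from 431 ± 2.06 to 466 ± 3.06 CPM (log2 fold change 0.11 ± 0.03, edgeR adjusted p = 0.0052). Jun (mm10 chromosome 4, 95049036 to 95052222), a partner of αNAC in transcription, fell from 35.0 ± 0.794 to 29.7 ± 0.183 CPM (-0.24 ± 0.04, edgeR adjusted p = 0.00017), and Fosl1 fell by 0.52. The other AP-1 genes that passed rose, including Junb (0.31 ± 0.07) and Jund (0.20 ± 0.03). In the list 8 of 14 tested genes rose and 2 fell, as they did adjusted over the list alone, with a median of 0.13. Camera gave an adjusted p of 0.021, and adjusted p = 0.55 with an estimated correlation. The list's call was lost without DMSO replicate 2 (adjusted p = 0.0577, 3 genes higher) and without NU7441 replicate 3 (adjusted p = 0.0599), and the number that fell was 1 without DMSO replicate 1.

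Interferon-stimulated genes rose. Of 32 tested 26 were higher and 0 lower, 7 of them by at least 2-fold, with a median log2 fold change of 0.65, and adjusted over the list alone 26 were higher and 1 lower. Ifit1 rose by 1.39 ± 0.25 on the log2 scale (edgeR, adjusted p = 0.00061), Mx1 rose by 1.38 ± 0.30, Rtp4 by 1.07 ± 0.22, Ifit3 by 0.99 ± 0.19, Dhx58 by 0.72 ± 0.09 and Stat2 by 0.51 ± 0.06. Most of these had low counts: Ifit1 had 322, 152 and 262 counts in the DMSO samples and 822, 372 and 552 in the NU7441 samples. Camera gave the list an adjusted p of 1.5e-07, and adjusted p = 0.55 with an estimated correlation. A robust fit, chosen after seeing the data, called 16 of the 32 higher and gave adjusted p = 0.0885 for Ifit1 and 0.0776 for Rtp4. The number lower was 1 without NU7441 replicate 1. Ccl5, a chemokine, had a log2 fold change of 1.08 ± 0.29 (edgeR, adjusted p = 0.012), and that call was lost without DMSO replicate 2 (0.0583), without DMSO replicate 3 (0.0563) and without NU7441 replicate 1 (0.0588), where the log2 fold change of Ccl5 was 0.59. The remaining genes with the largest rises were Mmp13, a collagenase, from 26.6 ± 1.03 to 52.8 ± 0.356 CPM (0.99 ± 0.04), and Agt, which encodes angiotensinogen (0.95 ± 0.10). Nckap5l (2.21 ± 0.66) and Atp6v0d1 (1.09 ± 0.38) met the same rule through 1 library each, with 9994 counts in NU7441 replicate 2 against 750 to 1146 elsewhere, and 14174 in NU7441 replicate 3 against 2924 to 4606. Both calls were lost without that library, at log2 fold changes of 0.17 (adjusted p = 0.0643) and 0.07 (adjusted p = 0.25), and also without any 1 of the DMSO replicates (adjusted p from 0.0587 to 0.134). Mmp13 also belongs to the list of NF-kB targets and had its largest rise. Of the 22 tested NF-kB targets 6 rose, with Mmp13, Tnfaip2 (0.24 ± 0.04) and Csf1 (0.13 ± 0.03) among them, and 1 fell, as adjusted over the list alone (camera, adjusted p = 0.17). The number that rose was 3 without NU7441 replicate 3, and the number that fell was 0 without DMSO replicate 3 and 2 without NU7441 replicate 2.

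Ribosomal protein genes rose slightly while nucleolar factors of ribosome assembly fell. Of 52 tested ribosomal protein genes 45 were higher and 1 lower, with a median of 0.17, over all genes and as adjusted over the list alone. Rpl3 rose by 0.23 ± 0.02, Rpl5 by 0.22 ± 0.02 and Rplp0 by 0.18 ± 0.02, and the exception was Rpl34 (-0.43 ± 0.09), named after its value was seen, at 6.45 ± 0.124 CPM in DMSO. Of 28 ribosome biogenesis genes 24 fell and 1 rose (26 and 1 adjusted over the list alone), with a median of -0.29, among them Dkc1 (-0.49 ± 0.04), Nop58 (-0.40 ± 0.03) and Ddx21 (-0.38 ± 0.03). Camera gave adjusted p values of 6e-15 and 1.3e-10, which became adjusted p = 0.27 and adjusted p = 0.29 with an estimated correlation. The biogenesis gene that rose was Polr1c (0.09 ± 0.03), named after its value was seen, and the number that rose was 0 without DMSO replicate 1, DMSO replicate 2, DMSO replicate 3, NU7441 replicate 2 or NU7441 replicate 3. Many ribosomal protein genes have processed pseudogenes that can take part of their reads, so that their single values are uncertain.

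Most chaperones of the endoplasmic reticulum and some ATF4 targets fell. Of 20 chaperone genes 14 were lower and 0 higher (16 and 1 adjusted over the list alone), with a median of -0.24, and Calr went from 970 ± 26 to 703 ± 52.9 CPM (-0.46 ± 0.04), Hsp90b1 from 1217 ± 12.5 to 966 ± 20.3 (-0.33 ± 0.02) and Pdia3 by -0.24 ± 0.03 on the log2 scale. Of 30 ATF4 targets 15 were lower and 0 higher (18 and 1 adjusted over the list alone), with a median of -0.12, and the enzymes of serine and one-carbon metabolism Phgdh (-0.44 ± 0.03) and Shmt2 (-0.49 ± 0.04) and the amino acid transporter Slc7a1 (-0.30 ± 0.03) were among them. Camera gave adjusted p values of 8.6e-06 and 0.00039, which became adjusted p = 0.54 and adjusted p = 0.64 with an estimated correlation. Without DMSO replicate 3, 1 ATF4 target was higher and 10 were lower. With each library left out in turn, the number of ATF4 targets lower lay between 10 and 19.

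FOXO targets, genes held down when PI3K and AKT signalling is high, rose in part. Tcp11l2 rose by 0.63 ± 0.05, Irs2, an adaptor of the insulin receptor, by 0.48 ± 0.06 and Fbxo32 by 0.46 ± 0.04. Of 19 tested 11 were higher and 0 lower, also as adjusted over the list alone, with a median of 0.15 (camera, adjusted p = 0.00094, and adjusted p = 0.18 with an estimated correlation), and 1 was lower without NU7441 replicate 1. Of 35 lysosome and autophagy genes 22 were higher and 5 lower, over all genes and as adjusted over the list alone, with a median of 0.13. Map1lc3b (0.31 ± 0.03), Ctsl (0.30 ± 0.03) and Ctsb (0.23 ± 0.03) rose, and Atp6v0d1 is counted among the 22 through its 1 high library. Camera gave an adjusted p of 0.00083, and adjusted p = 0.34 with an estimated correlation. Without NU7441 replicate 3 the number higher was 14. The number lower was 3 without DMSO replicate 1, DMSO replicate 2, NU7441 replicate 1 or NU7441 replicate 2 and 2 without DMSO replicate 3.

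Many contractile genes and some TGF-beta target genes rose as well. Tagln went from 146 ± 7.32 to 247 ± 7.16 CPM (0.76 ± 0.04), and Acta2 (0.36 ± 0.04) and Vim (0.33 ± 0.03) rose. In the list of SRF and myofibroblast genes 15 of 22 were higher and 0 lower (16 and 0 adjusted over the list alone), with a median of 0.18 (camera, adjusted p = 6.7e-06, and adjusted p = 0.29 with an estimated correlation). Of 23 BMP and TGF-beta targets 12 were higher and 0 lower, also as adjusted over the list alone, with a median of 0.12 and with Ltbp2 (0.49 ± 0.04), Fst (0.42 ± 0.03) and Tgfbi (0.25 ± 0.04) as examples (camera, adjusted p = 0.00061, and adjusted p = 0.29 with an estimated correlation). The number of these targets that were higher lay between 8 and 11 with each library left out. It was 8 with library size only and 12 with the other scalings. Other matrix genes went both ways, 12 of 33 higher and 8 lower (13 and 9 adjusted over the list alone), with Thbs1 (0.41 ± 0.02) and Bgn (0.26 ± 0.02) higher and Col6a3 (-0.26 ± 0.02) lower (camera, adjusted p = 0.17). A robust fit, chosen after seeing the data, left 5 matrix genes lower.

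The other lists were not called by camera. Of 21 tested Wnt genes 4 rose and 5 fell (4 and 7 adjusted over the list alone), with Dkk3 (0.32 ± 0.03) and Sfrp2 (0.29 ± 0.03) higher and Ccnd1, which encodes cyclin D1, lower (-0.41 ± 0.03, camera adjusted p = 0.41), and 9 fell without NU7441 replicate 2. Immediate early genes had 9 of 27 higher and 4 lower, also as adjusted over the list alone, with Klf2 higher (0.68 ± 0.08) and Myc lower (-0.32 ± 0.06), and a camera adjusted p of 0.29. The number higher was 4 without DMSO replicate 2, 3 without DMSO replicate 3 and 4 without NU7441 replicate 3. Of 28 hypoxia and glycolysis genes 1 rose, Ndrg1 (0.35 ± 0.04), and 9 fell, with Hk2 (-0.34 ± 0.05) and Pgam1 (-0.25 ± 0.03) among them (2 and 9 adjusted over the list alone). Camera gave an adjusted p of 0.098, which became 0.0251 without DMSO replicate 2 and 0.00563 without NU7441 replicate 1, and 2 rose without NU7441 replicate 3. Of 30 sterol and fatty acid synthesis genes 1 rose and 3 fell, also as adjusted over the list alone, with Stard4 lower (-0.23 ± 0.04). Camera gave an adjusted p of 0.53, which became 0.015 without NU7441 replicate 1, where 0 rose and 6 fell. The number that rose was 0 without DMSO replicate 2 and 2 without DMSO replicate 1, NU7441 replicate 2 or NU7441 replicate 3.

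Of 24 NRF2 targets 4 rose, with Gstm1 (0.29 ± 0.03) and Fth1 (0.21 ± 0.02) among them, and 5 fell, with Txnrd1 (-0.19 ± 0.03) among them, also as adjusted over the list alone. The median was 0.01, the mean -0.01 and the direction of camera up (adjusted p = 0.96). The number that fell was 3 without DMSO replicate 1 or 2 and 2 without NU7441 replicate 2 or 3. With upper-quartile scaling 7 NRF2 targets rose and 3 fell, and with the replicate block 7 rose and 7 fell. Of 8 aryl hydrocarbon receptor targets 2 rose, with Ahrr (0.34 ± 0.07) the larger, and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.53). The number that rose was 4 without DMSO replicate 1 and 1 without DMSO replicate 2, and the number that fell was 2 without NU7441 replicate 1 and 0 without DMSO replicate 1, DMSO replicate 2, NU7441 replicate 2 or NU7441 replicate 3. Markers of other cell types had few counts: 0 of 5 adipocyte genes (camera, adjusted p = 0.34), 0 of 5 skeletal muscle genes (camera, adjusted p = 0.96) and 0 of 5 endothelial genes (camera, adjusted p = 0.53) passed edgeR's test. At an unadjusted p under 0.05 edgeR had 2 adipocyte, 0 skeletal muscle and 2 endothelial genes, DESeq2 called 0 of the 4, 1 and 4 it tested, and limma-voom called 1 adipocyte gene and 0 in the others. With upper-quartile scaling edgeR called 2 adipocyte genes and 1 endothelial gene higher, and with the replicate block or the robust fit 1 of each. Among endothelial genes 1 fell without DMSO replicate 1 and 1 rose without NU7441 replicate 1, and 1 skeletal muscle gene fell without NU7441 replicate 3. For skeletal muscle the median was 0.23, the mean -0.07 and the direction of camera up. Of 7 leukocyte and osteoclast genes 1 rose, Cd14 (0.52 ± 0.15, edgeR adjusted p = 0.016, and 0.0537 without DMSO replicate 3), and 0 fell, also as adjusted over the list alone (camera, adjusted p = 0.53). The number that rose was 2 without DMSO replicate 2 or NU7441 replicate 1 and 0 without DMSO replicate 3. Of 12 chondrocyte genes 2 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.53), with Sox9 at 0.14 ± 0.03. In that list 1 rose without any 1 library but NU7441 replicate 2 or 3, and 0 fell without DMSO replicate 1, DMSO replicate 3 or NU7441 replicate 3.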

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

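The tests with halved counts, a robust fit, without Rn45s and Lars2, without genes with isolated count spikes and with groups that do not overlap were chosen after the data were seen. The number of called genes, 4231, lay between 3466 and 4407 under the other scalings, filters and tools and with each library left out. With halved counts the low-count filter kept 12957 genes instead of 13784, and 4288 were called. In that fit 24 of 29 tested interferon genes were higher.

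At an adjusted p of 0.01 the calls numbered 2805, of which 1191 were higher, because the threshold was stricter. With an estimated correlation camera called 0 of the 30 lists, where 4 had an unadjusted p under 0.05 and fry called 18. Upper-quartile scaling called 4407 genes, and the share higher was 56.5% against 45.9%; with library size only it was 37.7% of 4122. The median log2 fold change of all genes was 0.03 with upper-quartile scaling and -0.01 with library size only. DESeq2 called 3773 genes and limma-voom 4228. The number of lists called by camera lay between 12 and 15 with each library left out. Sets that leave out 1 library lose samples, and their calls lay between 3466 and 3910.

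With a replicate block 5120 genes were called, and 4224 of them were among the 4231. Samples with the same number had correlated deviations from their group means, at 0.13, 0.09 and 0.05, and every sample correlated best with its own number in the other group, a hint from the data and not from the design. Under the block Sp7 (adjusted p = 0.0492) and the hypoxia and glycolysis list (adjusted p = 0.0491) passed. Among named genes, none of the alternatives reversed a called direction. The robust fit lost 7 calls among named genes, those of Alpl, Ibsp, Ifit1, Ccl5, Rtp4, Nckap5l and Atp6v0d1, and the cause was not tested. Depth limits genes such as Bglap, with at most 12 counts per sample.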

Other observations

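The family tests, both counts of other sample splits, the tests of the deeper library, of Cdkn1a and of differences between cultures, and all tests of count spikes were chosen after the results were seen. The tests of length and GC content and of leukocyte markers were written before their results.

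Nucleoporin genes, which encode parts of the nuclear pore, fell in NU7441. Of 20 tested genes whose symbols are Nup followed by a number 18 were lower and 0 higher, with a median log2 fold change of -0.36, with Nup107 (-0.63 ± 0.04 SE), Nup85 (-0.55 ± 0.04) and Nup205 (-0.46 ± 0.03) among those lower (Fisher's exact test against all tested genes, two-sided, adjusted p = 1.1e-10 over 276 tests of 138 families, each the tested genes, at least 10, that share the letters before the first number of the symbol). Genes of the proteasome's regulatory particle also fell, 10 of 14 with the stem Psmd (median -0.18, Fisher's exact test adjusted p = 0.00038), as did 7 of 10 exosome genes with the stem Exosc (median -0.21, adjusted p = 0.0065), of which 5 passed with upper-quartile scaling. Centrosomal genes with the stem Cep were lower in 11 of 20 (Fisher's exact test, adjusted p = 0.0028). Kinesin genes with the stem Kif went both ways, 16 of 32 lower and 5 higher (Fisher's exact test for the fall, adjusted p = 0.00052). The 4 of them in the fixed lists, Kif11 (-1.41), Kif20a (-1.41), Kif23 (-1.46) and Kif2c (-1.38), belong to the mitosis list. The fall of this family is therefore partly that of the mitosis list. Outside that list Kif14 (-1.45) and Kif18b (-1.52) fell as far, while others that passed fell little, such as Kif5b (-0.12). Of 12 integrin alpha genes with a number after Itga 6 rose, Itga1 (0.30 ± 0.03) and Itga11 (0.29 ± 0.03) among them, and Itga8 fell (-0.36 ± 0.05), with an adjusted p of 0.044 by Fisher's exact test for the rise. In all 22 of the 276 tests passed, some of them because fewer genes changed than elsewhere, and the 6 families given here were picked from these. The medians of these families kept their sign under the other 3 scalings. Genes of a family are not independent, so these p-values are too small where members are regulated together.

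The 3 against 3 samples can be split in 10 ways, too few for a share under 0.05. The real split called 4231 genes and the highest of the others 1, so that 1 of the 10 splits gave as many. For gene lists camera called 13 in the real split and up to 17 in the others, and 3 of the 10 splits gave as many. The other splits put 2 samples of one group with 1 of the other, so that a difference between the groups stays in them. It widens the spread within each part and leaves some of the change. Their medians of the mitosis list lay between -0.60 and 0.40. Neither count therefore measures what chance alone would give.

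The 68 genes of the replication and mitosis lists had a median log2 fold change of -1.26. After a trend with gene length and GC content, fitted on genes outside these lists, was removed, the median was -1.25 (SD 0.35 over the members), and without the deeper library DMSO replicate 3 it was -1.28, which argues against either as the whole source. A rise of the p53 target Cdkn1a, an inhibitor of the cell cycle, was not seen either: its log2 fold change was -0.04 ± 0.03 (SE), with an upper 95% bound of 0.02. A candidate explanation that stays open is that fewer cells were cycling after 16 h of NU7441. Whether that comes from DNA-PK or from another kinase the compound may bind was not tested.

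The interferon list was higher in NU7441 by a median of 0.65. Relative to the DMSO mean the samples' medians were 0.15, -0.08 and -0.05 in DMSO and 0.84, 0.35 and 0.63 in NU7441. The difference of 2 samples was taken gene by gene, with its median over the list. All 9 pairs of a NU7441 and a DMSO sample differed in the same direction. The smallest such median was 0.13 and the largest between samples of one group 0.51, so differences between cultures may account for part of the rise and stay open. These pairs ignore the sample numbers, though in both groups replicate 1 had the highest median and replicate 2 the lowest. With the replicate block 27 of the 32 tested genes were higher and 1 lower. Whether a number marks a shared experiment is not given, so how much of the spread within a group is shared by number stays open. Leukocytes in the cultures are argued against by Ptprc, Cd52, Coro1a, Laptm5 and Tyrobp, which together stood at 0.19 ± 0.07 CPM (SD, n = 3) in NU7441 and 0.21 ± 0.08 in DMSO, a difference of -0.02, while the interferon list together rose by 137.8 CPM. An effect of NU7441 on interferon signalling remains a hypothesis.

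In 12 genes some libraries held counts far above the rest, 1 library in 10 of them, 2 in 1 and 3 in 1, by a rule of over 4 times the median of the other libraries, with 20 counts added to each, and at least 400 counts. Accn1 had 13254 counts in DMSO replicate 3 and 0 in the other samples, Bsn had 28136 in NU7441 replicate 2 against 424 to 658, and Tmem158 had 47684 to 73486 in DMSO replicates 2 and 3 and NU7441 replicate 2 against 170 to 212. Of the 12, 1, Tmem158 at 106 kb from Lars2, lay within 1 Mb of a gene with a mean of at least 100000 counts (upper exact 95% bound 38.5%). A further 8 lay at least 8.1 Mb away and 3 had none on their chromosome. For most of the set this argues against reads from a neighbour that abundant. The 1 Mb limit was set after the distances were seen. Less abundant neighbours were not examined, so reads from those stay open. The test run first went the other way without deciding: the median distance, 15.42 Mb, was shorter than the 48.5 Mb of random gene sets, at percentile 6.2 of 10000 sets. The source of the spikes stays open, and of the 8 that were tested 5 passed the threshold, among them Nckap5l and Atp6v0d1.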
